A study of Mus musculus with 4 samples.

How the data were processed

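RNA was measured on 4 single-colour Affymetrix mouse expression arrays, 1 array for each of 4 cultures of fetal liver progenitor cells from p53-deficient mice. The labels name the cultures as non-transformed or as transformed with H-RasV12 (an activated form of the small GTPase H-Ras), myr-Akt (AKT1 held at the membrane by an added myristoyl group) or c-Myc (a transcription factor). Per the labels' protocols, the cells grew in medium with 10% fetal bovine serum, 20 ng/ml EGF and 50 ng/ml HGF, and biotin-labelled cRNA was made from 1 µg of total RNA. Groups were taken from the labels alone. Each group holds 1 array, so no spread between replicates, standard error or p-value can be had, and the number of arrays limits the precision of every value. No label gives a scan date or a hybridisation batch, so a batch could not be told apart from the conditions.

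The deposited values are linear probe-set intensities that the authors made with MAS5, per the submitters' processing notes. The software version, detection calls and any filter are not given in the sources used here. The values themselves show that each array had been scaled, since the mean after trimming 2% at each end was 500.003 on all 4 arrays.

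From these intensities, each array was brought to a common 2% trimmed mean, signals under 20% of it (a signal of 100.001) were set to that floor, and log2 was taken. The floor was set before the data were examined, and values at it have no order. Of 45101 probe sets, 64 controls were left out of gene values. The platform annotation gave 1 gene symbol to 34958 probe sets, several to 932 and none to 9147, and no gene was named from the last 2 kinds. Of the single-gene probe sets, 34754 matched an Entrez identifier in the RefSeq gene table of mouse assembly GRCm38.p6, which was used for names only, and 0 symbols were updated. The single-gene probe set with the highest mean signal stood for each gene. Probe sets whose identifiers end in _s_at or _x_at can bind more than 1 transcript. This left 18193 genes, of which 10679 were above the floor on at least 1 array and 8965 on all 4. Genome positions are not reported because the value table names no genome build.

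A gene was counted as higher or lower when its log2 difference was 1 or more in size (2-fold) among those 10679 genes. A gene at the floor on 1 side of a comparison has only a bound, written as at least N-fold. Genes counted from 1 probe set were set against the gene's next brightest single-gene probe set.

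Before the data were examined, 32 gene lists were fixed, covering signalling outputs, growth, metabolism, differentiation, inflammation and markers of other cell types. For the 31 lists with 3 or more members above the floor on at least 1 array, the median log2 difference was given with its percentile among 10000 random lists of the same size, matched on mean log2 signal in 20 bins and drawn with replacement. A list at or above the 97.5 percentile or at or below the 2.5 percentile is said to stand apart. Members at the floor on 1 array entered at their bound, and members at the floor on both entered at 0. Members of a list are not independent, so the percentile describes these arrays and is no p-value. Across 6 contrasts there were 186 list comparisons. About 1.55 of 31 lists would stand apart in each contrast if their genes were random draws. The fixed lists are not such draws, so more than that may stand apart by chance. List members for which no single-gene probe set was named here were not analysed here.

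The rule for named genes was also fixed beforehand. It took, per comparison and direction, the 10 genes with the largest differences among those above the floor on both arrays and the 3 brightest of those at the floor on 1 array. It further took the 8 genes per direction shared most strongly by all 3 comparisons, the 5 per array and direction that stood farthest from the other 3 arrays, up to 4 members of each list that differed by at least 2-fold, and the transduced genes. Predicted or clone-named genes were left out, as were genes with a probe set of several symbols. A gene whose next brightest probe set differed by 2-fold or more the other way was to be left out too.

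The 3 comparisons share 1 control array, which alone makes them resemble one another. Unchanged arrays against one shared control were therefore simulated 100 times. The noise in that simulation came, in 10 bins of signal, from the difference between the arrays labelled myr-Akt and c-Myc (median SD 0.18 on the log2 scale). This pair was chosen after it was seen to be the closest, and its difference holds real differences as well as noise. The overlap of independent lists was computed as well.

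The counting step was tested on simulated data for the comparison of H-RasV12 with non-transformed over 10180 genes, with an assumed noise SD of 0.2. It recovered 100 of 100 4-fold and 100 of 100 8-fold differences and called 5 of 9980 unchanged genes. The differences were placed only in genes with mean signals far above the floor. At the assumed noise they were almost bound to pass the 2-fold limit, and recovery among dim genes was not tested. The list step, for the comparison of myr-Akt with non-transformed, called 5 of 200 unchanged lists and 200 of 200 lists shifted by 0.5. Those lists were drawn at random from simulated noise, so a low share of unchanged lists called was fixed in advance. The test does not show how lists of genes that move together behave on the real arrays.

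The 7 alternatives fixed before the data were examined were floors at 10% and 40% of the trimmed mean, a pseudocount in place of the floor, quantile normalization, scaling to the median log2 difference, the mean over all probe sets of a gene, and a 3-fold threshold. Leaving out each array in turn from the counts that use all 4 was added after the data had been seen. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.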

Results

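The data are the transcript profiles of 4 cultures of mouse fetal liver progenitor cells lacking p53. These cells can give rise to hepatocytes and bile duct cells. The series compares cells transformed by an oncogene with non-transformed cells, with 1 array for non-transformed cells and 1 each for cells labelled H-RasV12, myr-Akt and c-Myc. Without replicates, every difference given here is between arrays and was not set against a spread between cultures. Of the genes measured, 10216 were above the signal floor on the non-transformed array, 9927 on the array labelled H-RasV12, 9512 on that labelled myr-Akt and 9492 on that labelled c-Myc. The 5′ to 3′ signal ratio of the beta-actin control, a measure of RNA integrity, lay between 0.846 and 0.907.

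The transduced genes were looked at first, as a check of the labels. Myc, measured by 1 probe set, had a signal of 2285 on the non-transformed array, 1747 on the array labelled H-RasV12, 639.7 on that labelled myr-Akt and 420.6 on that labelled c-Myc, so it was lowest on the array whose label names it. Akt1 had a signal of 1870 in non-transformed cells and of 2760, 2834 and 2991 on the arrays labelled H-RasV12, myr-Akt and c-Myc, so it did not single out the myr-Akt culture. Whether these probe sets can detect the introduced sequences is not given in the sources used here. If they cannot, the signals are those of the endogenous genes and check nothing. Hras and Trp53 were not analysed here. Whether the Myc signal goes against its label thus stays open. Cultures are called by their labels throughout, and each direction given for the array labelled c-Myc rests on that label.

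In the comparison of H-RasV12 with non-transformed cells, the lists of hepatocyte and epithelial genes stood above their matched random lists. At least 2-fold higher were 8 of 17 and 6 of 12 measured members, out of 37 and 27 with a single-gene probe set. The mesenchymal list stood below, with 12 of 31 at least 2-fold lower. Apoa1, the main apolipoprotein of HDL, was 6.74 times higher, with a signal of 4300 against 638.2, and Krt8, a keratin of simple epithelia, was 5.73 times higher. Afp, the fetal counterpart of albumin, was at least 5.68 times higher. Dcn, which encodes the collagen-binding proteoglycan decorin, was 60.8 times lower, at 172.2 against 10469, and Saa3, an acute-phase protein, was 35.2 times lower. In all, 222 genes were at least 2-fold higher and 670 at least 2-fold lower.

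Other genes among the highest in this comparison were Clmp, an adhesion molecule (log2 difference 2.39), Ank3, which encodes ankyrin-G (2.32), Gldc, an enzyme of glycine breakdown (2.30), Sorbs2 (2.29), Syt12 (2.27), Esam, an adhesion molecule of endothelial junctions (2.24), Tmem59l (2.18) and Rasgef1b (2.16). Pcdh17, a protocadherin, was at least 7.00 times higher and Gdf10, a ligand of the TGF-beta family, at least 5.57 times. The lowest included Cemip (-5.51), which takes part in hyaluronan breakdown, the complement protease gene C1s1 (-5.26), Gpm6a (-4.01), Ogn (-3.92), the basement membrane gene Nid2 (-3.81), the folate receptor gene Folr1 (-3.73), Igfbp2 (-3.72) and Loxl1 (-3.71), a collagen and elastin crosslinking enzyme. Rspo1, which amplifies WNT signalling, was at least 36.8 times lower, Lrrn4 at least 21.2 times and Lcn2, an iron-siderophore binding protein, at least 16.7 times. The next brightest probe sets of Dcn and Cemip fell to the floor and could show no more than -0.22 and -0.47, while those of Gpm6a and Ogn were at -3.87 and, bound by the floor, -3.68.

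Of the fixed lists, 8 stood above and 9 below their matched random lists in the comparison of H-RasV12 with non-transformed. Of 17 measured hepatocyte genes, 8 were at least 2-fold higher and 1 lower, with a median log2 difference of 0.81 (percentile 100). Besides Apoa1 and Afp, Ttr, a carrier of thyroid hormone, was at least 4.76 times higher, whereas Gpc3, a glypican of fetal liver, was 11.5 times lower. Most of these genes were dim: 16 of the hepatocyte genes were above the floor on the array labelled H-RasV12 and 9 in non-transformed cells. Of 37 with a single-gene probe set, those under the floor on every array were left out. Members at the floor in non-transformed cells could only come out unchanged or higher, so the share of higher members follows in part from how members were chosen. Of 12 epithelial junction and keratin genes, 6 were at least 2-fold higher and 0 lower (median 0.96, percentile 100), among them Krt18 (1.54), Cdh17 (at least 3.85 times) and Cdh1 (1.18), which encodes E-cadherin. Biliary and progenitor genes had a median of 0.00 and did not stand apart, with Cd24a at 1.40, Sox9 at 1.00 and Krt7 at -1.68.

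Of 24 genes of ERK pathway output, which are induced by RAS and MAPK signalling, 5 were at least 2-fold higher and 0 lower on the array labelled H-RasV12 (median 0.53, percentile 100). They included Etv4 (1.93), Tgfa (at least 2.21 times), Ereg (1.05) and Dusp4 (1.05). Growth lists shifted with few members past 2-fold: ribosome biogenesis and MYC targets had a median of 0.65 with 1 of 38 members past it (Tfrc, the transferrin receptor gene, at 1.18), DNA replication 0.55 with 2 of 28 (Fen1 at 1.09 and Gins1 at 1.05), and mitosis 0.37 with 0 of 29. NRF2 targets, which handle oxidative stress, had a median of 0.35 (percentile 99.9), with Osgin1 at 1.77, Abcc4 at 1.62 and Gclc at 1.07 but Gstm2 at -1.43.

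The mesenchymal, interferon and cytokine lists stood below on the array labelled H-RasV12. Of 31 mesenchymal genes, 12 were at least 2-fold lower and 0 higher (median -0.48, percentile 0), including S100a4 (-3.68) and Col6a2 (-3.06). Of 13 stellate and mesothelial markers, genes of the liver's pericytes and its surface lining, 6 were lower and 0 higher (median -0.81, percentile 0), including Upk3b (-3.55), Des (-2.29) and Msln (-1.34). A different mix of cells in the H-RasV12 culture was not tested. RNA of a whole culture cannot tell it apart from changed expression, here or for the hepatocyte and epithelial lists. Of 24 interferon response genes, 11 were lower (median -0.82), among them Gbp2 (at least 7.57 times lower), Irgm1 (-1.99), Gbp3 (at least 3.79 times lower) and Igtp (-1.82). Of 22 cytokines and chemokines, 8 were lower and 2 higher (median -0.49), with Ccl7 at -3.12 and Il18 at -2.99. TGF-beta and YAP targets had a median of -0.60, with Gadd45b at -2.04 and Ltbp2 at -1.69, and WNT targets of -0.63, with Ccn4 at -1.50. FOXO targets, which active AKT represses, had a median of -0.52, with Selenop at -1.68 and Txnip at -1.29. The growth factor list had a median of -0.37, with Igf2 at -2.68, Igfbp6 at -2.59 and Btc at 2.06, and the ATF4 and unfolded protein response list of -0.26, with Atf3 at -1.84. The 4 endothelial markers measured had a median of 0.61 (percentile 97.9), with Flt1 at 1.22. That list no longer stood apart with a floor at 10% of the trimmed mean (median -0.004), with one at 40% (0.35) or with the mean over probe sets (0.16), and the growth factor list no longer did with the mean over probe sets (-0.14). Of 366 called genes with a further probe set, 358 differed in the same direction by it and 208 by at least 2-fold. The count of higher genes was 136 with a pseudocount in place of the floor, and that of lower genes 436 with the mean over probe sets.

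**Figure D1:**
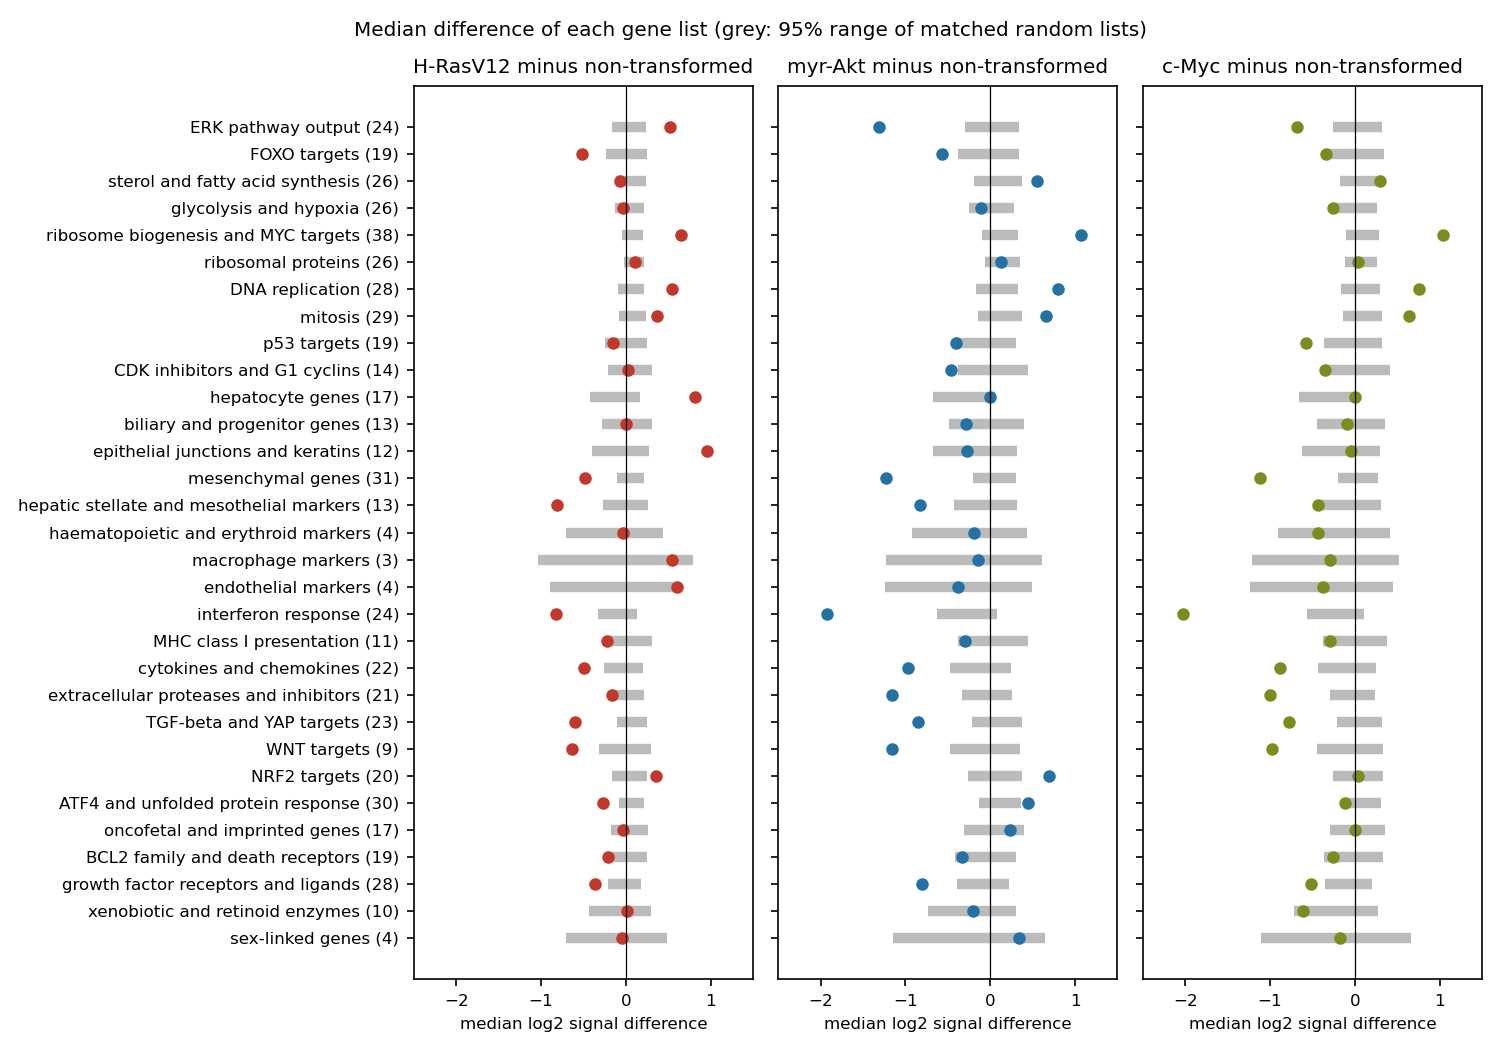
Median log2 signal difference from the non-transformed array (x axis) for each gene list, with the number of measured members in brackets, for the arrays labelled H-RasV12 (left), myr-Akt (middle) and c-Myc (right). Grey bars span the range of 10000 matched random lists within which a list does not stand apart; the ERK list lies at 0.53, -1.32 and -0.69.

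In the comparison of myr-Akt with non-transformed cells, the lists for ERK output, mesenchymal genes and interferon response stood below their matched random lists, and those for ribosome production and DNA replication stood above. Msln, a mesothelial surface protein, was 32.9 times lower, at 238.3 against 7837, Dusp4, a phosphatase induced by ERK, was 16.7 times lower, and Crabp1, a retinoic acid binding protein, was at least 49.3 times lower. Plac1, a placental gene, was 13.6 times higher, at 3348 against 245.4, and Igfbp5, a binding protein for insulin-like growth factors, was at least 40.5 times higher, at 4052 against 18.3. In all, 523 genes were at least 2-fold higher and 1353 at least 2-fold lower.

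Further genes among the highest on the array labelled myr-Akt were Smpdl3b (3.51), Lgals2, a galectin (3.41), Cdkn1c, a CDK inhibitor (3.31), Smtnl2 (2.93), Hoxd8 (2.78), Ppargc1b, a coactivator of mitochondrial genes (2.65), Kyat3 (2.63), Ydjc (2.33) and Crip2 (2.33). Fgf21, a metabolic hormone, was at least 10.0 times higher and Depp1, a FOXO-regulated gene, at least 9.73 times. The next brightest probe sets of Igfbp5 and Lgals2 were at the floor in non-transformed cells and higher by at least 0.33 and 0.19, bounds short of 2-fold. The lowest included Prkg2, a cGMP-dependent kinase (-4.72), Mgp, an inhibitor of calcification (-4.71), the interferon-induced Ifi27 (-4.49), Dpysl3 (-4.37), the protease Adamts12 (-4.16), the tetraspanin Tspan8 (-4.07), S100a4 (-4.00) and Loxl1 (-3.99). C1s1 was at least 50.1 times lower and Dkk1, a secreted WNT inhibitor, at least 26.9 times.

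Of the fixed lists, 6 stood above and 11 below in the comparison of myr-Akt with non-transformed. Of 24 ERK output genes, 14 were at least 2-fold lower and 0 higher (median -1.32, percentile 0), including Ereg (-3.87), Ccnd1, which encodes cyclin D1 (-3.83), and Hmga2 (-3.63). Of 38 ribosome biogenesis and MYC target genes, 20 were at least 2-fold higher and 0 lower (median 1.07, percentile 100), including Tfrc (1.98), Rrp9 (1.43), Ppat (1.42) and Cad (1.41), although Myc itself was 3.57 times lower. Ribosomal protein genes had a median of 0.13 and did not stand apart, with Rpl14 at 1.18. DNA replication genes had a median of 0.80 with 12 of 28 at least 2-fold higher, among them E2f2 (at least 5.99 times), Cdc6 (1.47) and Gins1 (1.39), and mitosis genes of 0.66, with Bub1b at 1.30 and Ccna2 at 1.03. Sterol and fatty acid synthesis genes had a median of 0.55 (percentile 99.9), with Dhcr7 at 1.24, Elovl6 at 1.09, Stard4 at 1.07 and Lss at 1.05. Of 20 NRF2 targets, 9 were at least 2-fold higher and 0 lower (median 0.69), with Gstm1 at 2.05, Abcc4 at 1.80 and Gclm, a subunit of the enzyme that begins glutathione synthesis, at 1.54. The ATF4 and unfolded protein response list had a median of 0.45 (percentile 99.6), with Atf3 at 1.57 and Herpud1 at 1.54 but Atf5 at -1.33.

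FOXO targets had a median of -0.57 on the array labelled myr-Akt, with 6 of 19 at least 2-fold lower, among them Pdk4, which restrains glucose oxidation (at least 13.0 times), Selenop (-3.32) and Txnip (-2.25). Of 24 interferon response genes, 19 were lower and 0 higher (median -1.93), including Xaf1 (at least 19.7 times) and Irgm1 (-3.39). Of 31 mesenchymal genes, 18 were lower and 2 higher (median -1.23), including Mmp2, a gelatinase (-3.87), and Bgn (-3.17). Stellate and mesothelial markers moved with them, with a median of -0.83 and 6 of 13 lower, among them Des (-3.30), Pdgfrb (at least 7.70 times lower) and Rgs5 (at least 6.23 times lower). Extracellular proteases and their inhibitors had a median of -1.16, with Adam19 at -2.70 and Timp1 at -2.62, and cytokines and chemokines of -0.97, with Il11 at least 11.7 times and Tgfb1 at least 11.2 times lower. TGF-beta and YAP targets had a median of -0.85, with Tgfbi at least 19 times lower and Ankrd1 at -2.18, and WNT targets of -1.16, with Cd44 at -2.90. The growth factor list had a median of -0.81, with Igfbp7 at -2.73, and the list of CDK inhibitors and G1 cyclins of -0.46. Of 14 genes in the latter, 4 were at least 2-fold lower, among them Ccnd1, given above, Cdkn2b (-1.97) and Cdkn2a (-1.26). The 1 gene at least 2-fold higher was the CDK inhibitor gene Cdkn1c (3.31). Hepatocyte genes had a median of 0.00, with 4 of them above the floor on this array and 9 in non-transformed cells, and Apoa1 was at least 6.38 times lower. Krt18 was 11.5 times lower and Krt8 at least 6.01 times, while the epithelial list did not stand apart (median -0.27). With the mean over probe sets, 3 lists no longer stood apart, at -0.28 for FOXO targets, -0.31 for CDK inhibitors and G1 cyclins and 0.31 for the ATF4 list. The count of higher genes was then 341. Of 800 called genes with a further probe set, 779 differed in the same direction by it and 477 by at least 2-fold.

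In the comparison of c-Myc with non-transformed cells, the lists for ribosome production, replication, mesenchymal genes and interferon response stood apart in the same directions as for myr-Akt. Smpdl3b, a membrane phosphodiesterase, was 20.2 times higher, at 3710 against 183.9, and Dlk1, a surface protein of fetal liver progenitors, was 16.3 times higher, at 1898 against 116.7. Il33, an alarmin cytokine, was 71.7 times lower, at 118.8 against 8515, and Cthrc1, a secreted matrix-associated protein, was 43.5 times lower. In all, 472 genes were at least 2-fold higher and 1211 at least 2-fold lower.

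Further genes among the highest on the array labelled c-Myc were Plac1 (3.52), Smtnl2 (3.22), Aldoc, a glycolytic aldolase (2.86), Prph, an intermediate filament gene (2.75), Ppargc1b (2.72), the tight junction gene Cgn (2.67), Fndc3c1 (2.66) and Prg4, which encodes lubricin (2.61). Depp1 was at least 10.8 times higher, Sfrp2, a secreted WNT modulator, at least 10.2 times and the nuclear pore gene Nup210 at least 9.25 times. The lowest included Aplp1 (-4.60), Msln (-4.49), Crispld2 (-4.46), Adam19 (-4.34), the growth factor gene Mdk (-4.26), Prkg2 (-4.12), Spon2 (-4.11) and Adamts12 (-4.00). Crabp1 was at least 49.3 times lower, Ifi27 at least 35.8 times and Plac8 at least 30.1 times.

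Of the fixed lists, 3 stood above and 13 below in the comparison of c-Myc with non-transformed. Of 38 ribosome biogenesis and MYC target genes, 21 were at least 2-fold higher and 0 lower (median 1.04, percentile 100), including Polr1b, a subunit of RNA polymerase I (1.70), Cad (1.68), Tfrc (1.52) and Nolc1 (1.39), while the array's Myc signal was 5.43 times lower. DNA replication genes had a median of 0.76 with 10 of 28 higher, among them Cdt1 and Gins1, both at 1.37, and mitosis genes of 0.64, with Bub1b at 1.08. Ribosomal protein genes (median 0.04), sterol and fatty acid synthesis (0.29), NRF2 targets (0.04, with a mean of -0.01) and the ATF4 list (-0.11) did not stand apart. Within the NRF2 list, Gstm1 was at 1.62 while Cbr3 was at -2.10 and Srxn1 at -1.56.

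Of 24 ERK output genes, 9 were at least 2-fold lower and 0 higher on the array labelled c-Myc (median -0.69, percentile 0), including Ereg (at least 17.3 times), Ccnd1 (-3.83) and Fosl1 (-3.34). Of 24 interferon response genes, 18 were lower and 0 higher (median -2.02), with Irgm1 at -3.41 and Ifit1 at least 10.6 times lower. Of 31 mesenchymal genes, 16 were lower and 0 higher (median -1.12), including Prrx1 (at least 19.3 times) and Mmp2 (-3.27). Stellate and mesothelial markers had a median of -0.43, with 6 of 13 lower, among them Des (at least 11.7 times) and Ecm1 (-2.73). Proteases and inhibitors had a median of -1.0, cytokines and chemokines of -0.89, TGF-beta and YAP targets of -0.77, WNT targets of -0.98 and the growth factor list of -0.52. In these lists Mmp10 was at least 4.63 times lower, Il18 was at -3.24, Pmepa1 at -2.25, Cd44 at -2.89 and Igfbp7 at -2.04, while Igf2, a fetal growth factor, was at 2.09. Genes activated by p53 had a median of -0.57, with 6 of 19 lower and 1 higher; Perp was at -2.89 and Cdkn1a, which encodes p21, was at least 4.55 times lower, but Pmaip1 was at 1.82. CDK inhibitors and G1 cyclins had a median of -0.35, with Cdkn1c at 2.18 and Cdkn2b at -1.92. FOXO targets had a median of -0.34 and glycolysis and hypoxia genes of -0.25, with Hk1 at -3.43 and Vegfa at -1.48. The FOXO list no longer stood apart with a floor at 10% of the trimmed mean (-0.34) or a pseudocount (-0.31), the glycolysis list with that floor (-0.25), quantile normalization (-0.20) or the mean over probe sets (-0.14), and the WNT list with a pseudocount (-0.66). The count of higher genes was 298 with a pseudocount and 293 with the mean over probe sets. Of 709 called genes with a further probe set, 700 differed in the same direction by it and 410 by at least 2-fold.

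**Figure D2:**
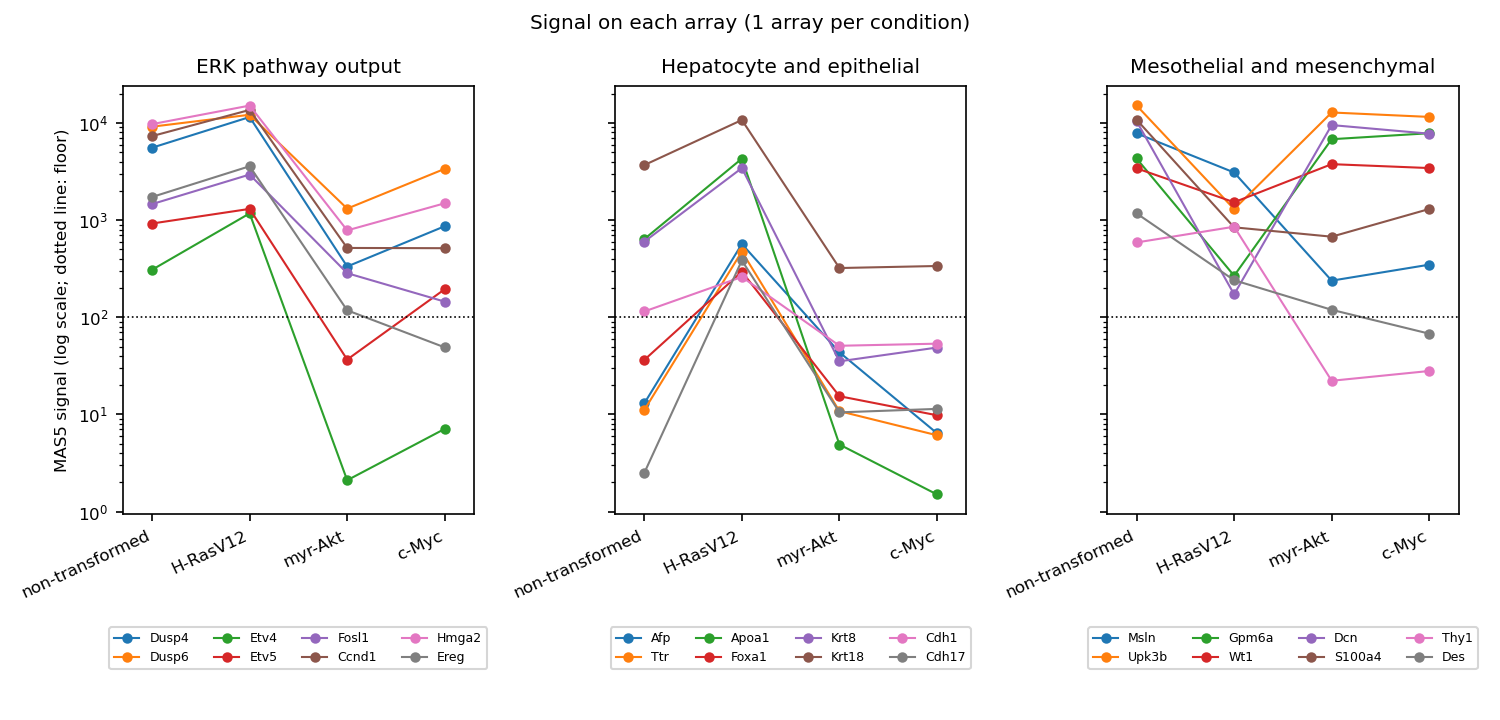
MAS5 signal (y axis, log scale) of 24 genes on the 4 arrays, in panels for ERK output (left), hepatocyte and epithelial genes (middle) and mesothelial and mesenchymal genes (right); each line is 1 gene, the dotted line is the floor of 100.001, and signals under it have no order. The genes drawn were chosen after their values were seen; Apoa1 lies at 638.2, 4300, 4.9 and 1.5 from left to right.

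Set beside one another, the arrays labelled myr-Akt and c-Myc were close and the array labelled H-RasV12 stood nearer to non-transformed cells. Across genes, which are not independent replicates, log2 signals correlated at r = 0.977 between myr-Akt and c-Myc, 0.943 between H-RasV12 and non-transformed, and between 0.898 and 0.907 for the other pairs. Directly compared, 378 genes were at least 2-fold apart between myr-Akt and c-Myc, 1467 between H-RasV12 and myr-Akt and 1482 between H-RasV12 and c-Myc. On both the non-transformed and the H-RasV12 array, 516 genes were at least 2-fold higher than on both other arrays, and 81 were lower. The other pairings of the arrays gave 12 and 0, and 40 and 3. For the first pairing the counts were 354 and 52 with the mean over probe sets and 228 and 22 with a 3-fold threshold. With a floor at 10% of the trimmed mean they were 695 and 107.

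The 3 comparisons shared 28 genes that were higher and 288 that were lower than in non-transformed cells. The 28 were 9 with a pseudocount in place of the floor and 13 with the mean over probe sets. The shared higher genes included Lgals2 (3.51, 10.6 and 5.61 times for H-RasV12, myr-Akt and c-Myc), Arhgap28 (2.75, 3.02 and 3.58 times), the phosphoinositide phosphatase gene Mtm1 (2.60, 4.07 and 3.86 times), Shmt1, an enzyme of one-carbon metabolism (2.32, 2.62 and 6.07 times), and Umps, which makes uridine monophosphate (2.31, 2.87 and 2.98 times). Hirip3, Syne4 and Snhg16 were also among them. The shared lower genes included Lcn2 (at least 16.7 times on each array), the potassium channel gene Kcnj15 (at least 10.9 times on each), the GABA receptor gene Gabrb1 (11.4, 13.6 and 9.67 times) and Myh11, the smooth muscle myosin heavy chain (9.58, at least 14.5 and at least 14.5 times). C1s1, Ramp1, the glutamate transporter gene Slc1a6 and Angptl7 were also among them. By the next brightest probe set, Shmt1 differed by 0.69, 0.14 and 1.75, Umps by 0.68, 0.70 and 0.97, Snhg16 by 0.52, 0.92 and 0.80, Lgals2 for c-Myc and Arhgap28 for myr-Akt by at least 0.24 from the floor, and that of Myh11 fell to the floor on each array and could show no more than -0.35. Independent lists would share 0.48 and 9.63 genes, and unchanged arrays against a shared control shared 0.54 and 0.62 on average, at most 3 and 4. A shared set is the same as the control array standing apart from the rest, and part of the excess may come from that single control. Without the array labelled H-RasV12, 303 and 978 genes were shared.

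Log2 differences from the control correlated across genes at r = 0.878 for myr-Akt with c-Myc, 0.415 for H-RasV12 with myr-Akt and 0.362 for H-RasV12 with c-Myc. Unchanged arrays sharing a control gave about 0.50, a value fixed by sharing 1 control with equal noise on each array, whatever its size. The covariances were 0.628, 0.224 and 0.189, against 0.041 in each simulated case. Genes shared by myr-Akt and c-Myc numbered 303 higher and 978 lower, where independent lists would share 23.1 and 153.4. For H-RasV12 with myr-Akt they numbered 37 and 374 against 10.9 and 84.9, and for H-RasV12 with c-Myc 34 and 326 against 9.8 and 76.0. Those shared by unchanged arrays averaged between 1.94 and 2.72 in each direction.

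**Figure D3:**
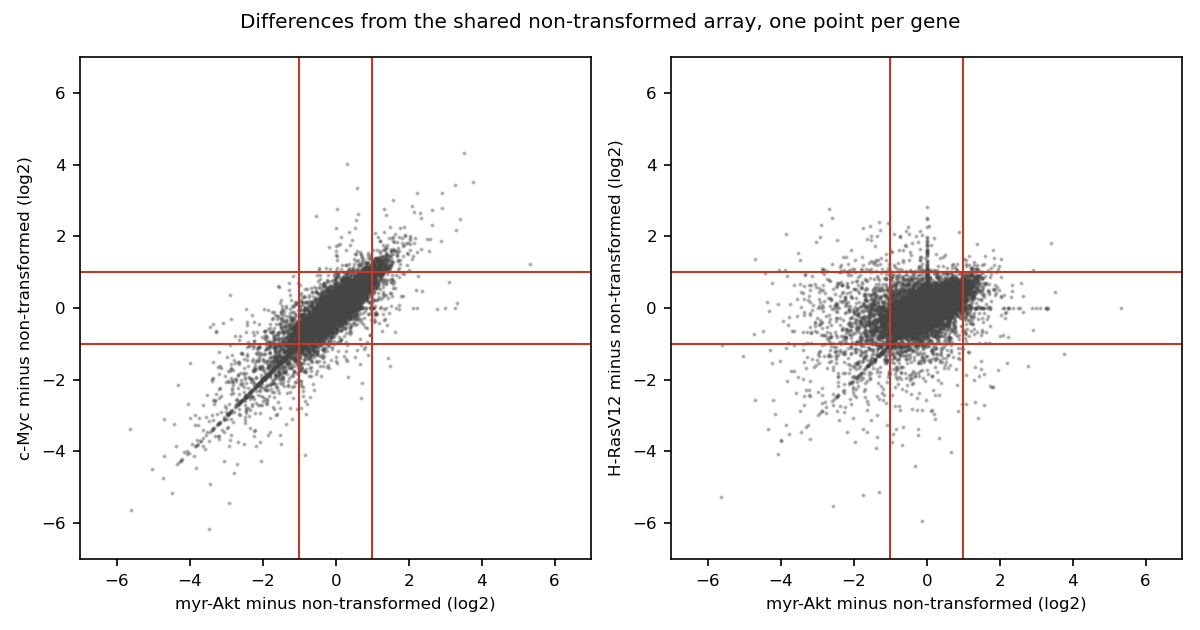
Log2 difference from the shared non-transformed array for the array labelled myr-Akt (x axis) against those labelled c-Myc (left, y axis) and H-RasV12 (right, y axis), 1 point per gene above the floor on at least 1 array; red lines mark a 2-fold difference. The correlation across genes is 0.878 on the left and 0.415 on the right, and points in straight runs are genes at the floor on 1 or more arrays.

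Genes that stood at least 2-fold apart from each of the other 3 arrays numbered 159 higher and 163 lower for H-RasV12, 45 and 72 for myr-Akt, and 31 and 64 for c-Myc. Those of H-RasV12 included Pcdh17, Apoa1, Krt8, Afp and Gdf10 as higher, and Dcn, Lrrn4, Gpm6a, Saa3 and the transcription factor gene Bnc1 as lower. Bnc1 had a signal of 462.1 there and of 5656, 7161 and 9470 in non-transformed, myr-Akt and c-Myc cells. Those of myr-Akt included as higher Igfbp5, Fgf21, Hoxd8, the claudin gene Cldn10 (801.6 against 89.6 or less elsewhere) and Aldh1a2, which makes retinoic acid (967.5 against 72.3 or less). As lower they included Cyba, a subunit of NADPH oxidase (267.0 against 2016 or more), Ank3, Nudt6, the kinase gene Ptk2b and Xist, the RNA that silences an X chromosome (559.5 against 4209 or more). Those of c-Myc included Dlk1, Sfrp2, Prph, Epb41l4b and the atrial myosin light chain gene Myl7 (1105 against 188.1 or less) as higher. As lower they included Il33, Cthrc1, Mdk, Parm1 and Col1a2, a chain of type I collagen (3578 against 15479 or more). The next brightest probe sets of Nudt6 and Parm1 were at the floor on the array singled out and lay at least 0.46 below H-RasV12 and at least 0.98 below myr-Akt. With a pseudocount, a floor at 40% of the trimmed mean and the mean over probe sets, those lower numbered 40, 47 and 40 for myr-Akt and 35, 34 and 30 for c-Myc; with the floor at 40%, 29 were higher for myr-Akt, with one at 10%, 103 were lower for c-Myc, and with the mean over probe sets, 104 were lower for H-RasV12. Without the c-Myc array, 185 genes were higher and 717 lower for myr-Akt, and without the myr-Akt array, 178 were higher and 662 lower for c-Myc. Without the non-transformed array, 771 were higher and 320 lower for H-RasV12 and 89 were higher for c-Myc, and without the H-RasV12 array, 146 were lower for myr-Akt.

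Against the mean of the other 2 transformed arrays, the ERK list had a median of 1.23 for H-RasV12, -1.25 for myr-Akt and -0.47 for c-Myc. The 3 contrasts of this kind sum to 0 for each gene, so a high value on 1 array lowers the others and they are not separate results. The median of sterol and fatty acid synthesis was -0.49 for H-RasV12 and 0.48 for myr-Akt, and 0.09, not apart, for c-Myc (0.15 and apart with the mean over probe sets). That of the NRF2 list was 0.64 for myr-Akt and -0.51 for c-Myc, and that of the ATF4 and unfolded protein response list 0.44 and -0.24. The ribosome biogenesis and MYC target list had a median of -0.36 for H-RasV12, 0.22 for myr-Akt and 0.17 for c-Myc. In these contrasts 12, 7 and 1 lists stood above and 4, 12 and 12 below for H-RasV12, myr-Akt and c-Myc.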

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

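All tests in this part were chosen after the results they bear on had been seen. The ERK output list moved in opposite directions in different cultures. It was higher on the array labelled H-RasV12 than on that labelled myr-Akt by a median of 1.64 on the log2 scale and than on that labelled c-Myc by 1.08. The ATF4 and unfolded protein response list also moved in opposite directions and differed by -0.38 between H-RasV12 and myr-Akt. With 1 array per culture these differences were not tested. Probe sets with no gene symbol or several stand outside the comparisons of the report. Of 2786 such probe sets above the floor, 199 were at least 2-fold from non-transformed on the array labelled H-RasV12, 334 on that labelled myr-Akt and 318 on that labelled c-Myc.

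The arrays divided into non-transformed with H-RasV12 and myr-Akt with c-Myc. A difference in RNA integrity would need unlike 5′ to 3′ ratios of the control transcripts, but their log2 range over the 4 arrays was 0.10. These ratios do not test labelling or hybridisation, which stay open. The median probe-set signal divided the arrays the same way, at 65.8 for non-transformed and 61.7 for H-RasV12 against 53.1 for myr-Akt and 51.7 for c-Myc. Scaling is argued against by quantile normalization, after which 569 genes still divided the arrays this way and 40 the next pairing. The explanation by other cells was tested first over all 13 stellate and mesothelial markers, whose differences from non-transformed had an interquartile range of 2.44. That width decides nothing, since 5 of the markers were at the floor on both arrays and the quartile nearest 0, at -0.20, is that of a marker that could fall no further. The explanation was then taken apart because the list holds 2 cell types, with genes assigned after their values were seen. The mean difference of myr-Akt and c-Myc from non-transformed ran from -4.77 to 0.76 over Wt1, Msln, Upk3b and Gpm6a, a range of 5.53. Fewer mesothelial cells alone would lower all 4 alike, which these values argue against. They had already been seen, and fewer such cells together with changed expression of single genes stays open. Fewer stellate cells also stays open. The other 9 markers, counted as stellate only because they are not among those 4, had a median of -1.96 or lower. Hand2 and Alcam, far above the floor, were at only -0.83 and -0.74 for myr-Akt and -0.43 and -0.26 for c-Myc. A lower ERK output in myr-Akt and c-Myc cells stays open too, since the list's median of -0.99 against the other pair restates values of the report and is no separate support. The abundant matrix transcripts give no single answer, with Dcn and Col3a1 at -0.14 and -0.47 for myr-Akt and -0.43 and -0.91 for c-Myc but Col1a1 at -2.25 and -2.54, and a batch effect could not be tested.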

How the results depend on the processing

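Leaving out each array in turn was chosen after the data had been seen; the other alternatives were fixed beforehand. Under the alternatives fixed beforehand, 98 counts of genes were made again: 68 lay within 1.5 times the reported count and 30 did not, and both other scalings of the arrays left all 14 counts within it. For the named genes and the list members at least 2-fold apart, 3462 alternative values kept their side of 2-fold, 293 dropped under it and 1 passed it. Apart from some values of Akt1 and Myc, all had started past 2-fold, so hardly any could newly pass it. List members under 2-fold were not followed singly. Of the gene lists, 1041 alternative values over 6 contrasts kept their side of the percentile limits, 32 no longer stood apart and 37 newly did. Of these genes, none past 2-fold turned its sign, and no list stood apart in opposite directions, but the median of the endothelial markers for H-RasV12 changed sign with a floor at 10% (0.61 to -0.004). Called genes that are neither named nor in a list entered the counts alone. Lists gained most often were MHC class I presentation for H-RasV12 and, against the other 2 transformed arrays, the growth factor list for H-RasV12, under 5 alternatives each, and the list lost most often was that of WNT targets for H-RasV12 against the other 2, also under 5. The share of higher genes moved by under 10 percentage points with the scaling. The signal floor limits what dim genes show: 8965 of 10679 genes were above it on all 4 arrays.

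With a pseudocount in place of the floor, 136 genes were higher for H-RasV12, 298 for c-Myc and 9 for all 3 cultures, and those lower than on the other 3 arrays numbered 40 for myr-Akt and 35 for c-Myc. With the mean over all probe sets of a gene, 436 were lower for H-RasV12, 341 were higher for myr-Akt, 293 for c-Myc and 13 for all 3, and those lower than on the other 3 arrays numbered 104 for H-RasV12, 40 for myr-Akt and 30 for c-Myc. With a floor at 40% of the trimmed mean, those apart from the other 3 arrays numbered 29 higher and 47 lower for myr-Akt and 34 lower for c-Myc, and with a floor at 10%, 103 were lower for c-Myc. For these settings the cause was not tested. A 3-fold threshold, which admits fewer genes by construction, gave 58 higher and 268 lower for H-RasV12, 85 and 648 for myr-Akt, 88 and 578 for c-Myc, 1 and 93 for all 3, and apart from the other 3 arrays 52 and 65 for H-RasV12, 14 and 13 for myr-Akt, and 15 and 17 for c-Myc.

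Leaving out 1 array removes a condition that a gene has to meet. The genes shared by the remaining transformed arrays then numbered from 34 to 303 higher and from 326 to 978 lower. Those apart from all remaining arrays numbered from 163 to 771 higher and from 195 to 320 lower for H-RasV12, from 54 to 185 higher and from 79 to 717 lower for myr-Akt, and from 33 to 178 higher and from 74 to 662 lower for c-Myc. No paired analysis was possible because each group has 1 array.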

Other observations

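Of the tests in this part, the one on genes that escape X inactivation was fixed before its result was seen and the others after. Several of the lists fixed beforehand moved little or held few measured genes. Imprinted and oncofetal genes had medians of -0.04, 0.24 and 0.00 for H-RasV12, myr-Akt and c-Myc and did not stand apart, but single members moved far: Meg3, an imprinted noncoding RNA, was at -3.01 for myr-Akt and -2.79 for c-Myc, and Igf2 was at -2.68 for H-RasV12 and 2.09 for c-Myc. The mean for myr-Akt was -0.06, of the opposite sign to its median. Targets of p53, in cells that lack it, had medians of -0.15 and -0.40 for H-RasV12 and myr-Akt and did not stand apart there; Btg2 was at -2.38 for H-RasV12 and Perp at -3.02 for myr-Akt. Genes of the BCL2 family and death receptors had medians of -0.21, -0.33 and -0.26, and Bcl2, an inhibitor of apoptosis, was at 1.10 for H-RasV12, -2.00 for myr-Akt and -1.72 for c-Myc, the first of these chosen after its value was seen. MHC class I genes had medians of -0.22, -0.30 and -0.29, not apart, but the list stood below for H-RasV12 under 5 of 6 alternatives (percentiles 1.34 to 2.23, against 2.615 here) and for c-Myc with the mean over probe sets (-0.40), with Tapbp at -1.77 for H-RasV12 and H2-D1 at -1.67 for c-Myc.

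Biliary and progenitor genes had medians of -0.29 for myr-Akt and -0.10 for c-Myc, not apart, with Tspan8 at -4.07 and -4.00 and Sox9 at least 3.88 times lower in both. The epithelial list had a median of -0.04 for c-Myc and the hepatocyte list of 0.00, although Dlk1 was at 4.02. Xenobiotic and retinoid enzymes had medians of 0.02, -0.20 and -0.61, and glycolysis and hypoxia genes of -0.03 for H-RasV12 and -0.11 for myr-Akt. For H-RasV12, sterol and fatty acid synthesis (-0.07), proteases and inhibitors (-0.16), CDK inhibitors and G1 cyclins (0.03) and ribosomal proteins (0.10) did not stand apart. Markers of blood cells (4 measured, medians -0.03, -0.20 and -0.43) and of macrophages (3 measured, 0.54, -0.15 and -0.29) did not stand apart, nor did endothelial markers for myr-Akt and c-Myc (both -0.38), and the sex-linked list had medians of -0.04, 0.34 and -0.18. For myr-Akt the mean of that list was -0.48, opposite to its median, because of Xist. Of these lists, some stood apart under an alternative: biliary genes for myr-Akt (-0.64) and proteases for H-RasV12 (-0.16) with a floor at 40% of the trimmed mean, macrophage markers for H-RasV12 with one at 10% (0.89) or a pseudocount (0.46), the BCL2 list for H-RasV12 with the mean over probe sets (-0.21), and xenobiotic enzymes for c-Myc with a floor at 40% (-0.36) or quantile normalization (-0.61).

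Xist had a signal of 559.5 on the array labelled myr-Akt and of 6070, 6249 and 4209 on those labelled non-transformed, H-RasV12 and c-Myc. Noise of 1 probe set is argued against, since all 3 Xist probe sets were lower, 1 of them bound by the floor at -2.64 and the others at -2.70 and -3.44. A smaller share of cells with 2 X chromosomes may account for it, but the tests leave this open. The Y-linked genes were higher by a median of 0.48 (percentile 90.9), short of the limit. All 3 were highest on the array labelled myr-Akt, and against the mean of the other 2 transformed arrays the sex-linked list, which holds them and Xist, stood above (0.53, percentile 99.5), though not with a floor at 40% of the trimmed mean (0.22) or the mean over probe sets (0.23). The genes that escape X inactivation (Kdm6a, Eif2s3x, Kdm5c and Ddx3x) were at 0.57, 0.54, -0.21 and 0.39 for myr-Akt. Their median was higher by 0.46 (percentile 91.4), the opposite of what had been predicted and still within the range of random sets. In the same order they were at 0.78, 0.54, 0.04 and 0.40 for c-Myc, where Xist was at -0.53, and at 0.64, 0.51, -0.09 and 0.18 for H-RasV12. The rise of all but Kdm5c is thus not particular to myr-Akt and does not decide the question.

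Myc was lowest on the array labelled c-Myc. If the probe set detects the introduced gene, an exchange with the H-RasV12 or myr-Akt array would leave a high signal there, but the higher of those differences from non-transformed was -0.39. On the same premise the label as given fails too, with the array labelled c-Myc at -2.44, so this test cannot favour the labels. For an exchange with non-transformed the values point both ways. Against it, the ribosome biogenesis and MYC target list was higher on the other 3 arrays, with a lowest median of 0.65. But that list was as high for myr-Akt (1.07) as for c-Myc (1.04), so it does not single out MYC. The Myc signal itself was highest, at 2285, on the array labelled non-transformed, so this exchange stays open. An exchange with myr-Akt cannot be told apart from correct labels by Akt1, which differed by a median of 0.22 between the arrays labelled c-Myc and myr-Akt over 3 probe sets. A probe set that detects only endogenous Myc could not be tested without probe sequences.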
